A study of Mus musculus with 6 samples.

How the data were processed

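Gene expression was measured in B7.1-high medullary thymic epithelial cells of 3 wild-type and 3 Aire-deficient pools of mice, with 1 array per pool. Each pool held the thymi of 5 animals, so 15 animals stand behind each group, and per the labels the total RNA of the sorted cells was amplified in 2 rounds with T7 polymerase before hybridisation. Such amplification favours the 3' end of transcripts. The deposited values are linear signal intensity per probe set, given to 1 decimal, and the software, background correction and scaling behind them are not given in the sources used here. No detection calls were used here.

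Of 12488 probe sets, 66 controls were left out and 12422 were used. In the platform annotation 10833 of these had 1 gene, 396 had several and 1193 had none, and probe sets with several or none were not named. Of the former, 10817 matched a gene of the mouse assembly GRCm38.p6 by Entrez identifier, and 0 symbols had to be updated. That assembly served only for names and for which genes neighbour each other. One probe set stood for each of 8251 genes, the one with the highest mean log2 signal over all 6 arrays.

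The 2% trimmed means of the deposited arrays ranged from 19.6 to 26.9, more than the 5% allowed for using values as deposited, so the arrays were quantile normalized. Signals under the pooled 20th percentile, 1.8, were raised to that floor and log2 transformed. A gene was tested if it lay above the pooled 40th percentile, 5.53, on at least 3 of the 6 arrays, which removed 2301 genes and left 5950. The latter value is also the dim limit: where all 3 arrays of a group lay under it, the fold is given as "at least", the brighter group's geometric mean divided by the limit. A floor shortens the fold of dim genes. Signal correlations between arrays of a group averaged 0.836 to 0.916 per array.

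Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a variance trend), with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. All limma, camera and fry tests were 2-sided. Of 40 gene lists fixed from textbook knowledge, 31 with at least 5 tested genes were tested with camera (preset correlation 0.01, and again with an estimated correlation) and fry, adjusted over the 31; the union of the 22 tissue lists and the genes recalled from published work stand outside that family. The pools are separate samples of animals, so p-values measure the spread between pools, including amplification and hybridisation.

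The replicate numbers of the labels were checked for pairing. Deviations from the group means correlated at 0.38, 0.21 and 0.19 between arrays of the same number and at -0.26 to 0.075 between arrays of different numbers. Each same-number pair lay above 0.1, so the numbers were taken to pair the arrays; the pairing comes from these correlations, and the labels do not say what the numbers stand for. The gene lists described above and the fit without the block as the main one were chosen before the data were examined. So were the tests, except those said below to have been chosen or added after results were seen. The granulocyte marker list used below is not among those gene lists.

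Genes named in the text are Aire, the 12 largest falls and 12 largest rises among called genes whose groups did not overlap, up to 4 members of each list with the smallest p, the recalled genes, and a few said to have been chosen after their values were seen. Sex-linked genes and some of the other probe sets of named genes are given as checks. Alternatives were other scalings, floors, filters, variance models, array weights, rules for probe sets, the block and leaving out each array. A term for 3' bias, the block without both arrays numbered 2, and leaving out arrays with the 6-array gene set kept were added after the data were seen.

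The procedure was tested on simulated data for the Aire-deficient against wild-type comparison, with 200 of 5950 genes changed. It recovered 8% of 50 genes changed 2-fold, 52% of those changed 4-fold, 88% at 8-fold and 82% at 16-fold, with 4 false calls among 119, and made at most 1 call in 20 draws without a change. The simulated genes varied independently with normal noise, without pairing of arrays or 3' bias. These rates may therefore not hold for the real arrays. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.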

Results

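Medullary thymic epithelial cells were sorted from wild-type mice and from mice with both copies of Aire disrupted, and their RNA was hybridised to 1-colour oligonucleotide arrays. Aire is a transcriptional regulator of the thymic medulla, where epithelial cells transcribe many genes otherwise restricted to peripheral tissues. Each genotype was represented by 3 arrays, and each array by the pooled thymi of 5 animals of both sexes, 3 to 5 weeks old, from a mixed B6/129 F2 background. The sorted cells lacked the blood cell marker CD45, bound the epithelial antibody G8.8, stained at an intermediate level with CDR1 and stained strongly for B7.1, a costimulatory molecule. The array carried 12488 probe sets, of which 10833 named exactly 1 gene, and 5950 genes passed the filter on dim signals and were tested. Signals are in arbitrary units, group values are geometric means of normalized signals over 3 arrays, and SDs and SEs are on the log2 scale. The number of arrays limits the precision. Wild-type array 2 stood apart in its ratio of 3' to 5' beta-actin signal, which can reflect RNA quality or amplification: it was 95.8, against 4.38 to 13.8 on the other 5 arrays. The Gapdh ratio was 8, 87.9 and 26.3 on wild-type arrays 1 to 3 and 5.94, 10.9 and 16 on Aire-deficient arrays 1 to 3. In each same-number pair both ratios were higher in wild type (beta-actin 5.42 and 4.38, 95.8 and 5.75, 13.8 and 13.4). This sign of 3' bias thus ran with genotype and cannot be fully told apart from it.

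The single probe set for Aire gave a higher signal in the Aire-deficient cells. The signals were 59.9, 96.4 and 138 on the wild-type arrays and 202, 297 and 211 on the Aire-deficient arrays, so the groups did not overlap. The log2 difference was 1.33 ± 0.35 (SE), with an adjusted p of 0.0873 in the limma fit, which missed the threshold of 0.05. With the replicate number as a block the adjusted p was 0.0182, and on the values as deposited it was 0.0408. The labels do not say which part of the gene was disrupted, and the position of this probe set in the transcript is not given in the sources used here. This probe set therefore does not check the genotype labels.

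The comparison of the genotypes asked which transcripts of these cells depend on Aire. Transcripts of peripheral tissues formed a large part of those that fell. In the limma fit 79 genes were lower and 23 were higher in the Aire-deficient cells at an adjusted p under 0.05, so that 77.5% of the called genes were lower. Of the 79 lower genes, 33 belonged to 22 lists of tissue-restricted genes fixed in advance, that is 41.8%, against 4.2% of all tested genes (odds ratio 18.7, 95% interval 11.3 to 30.5, 2-sided Fisher's exact p = 1.58e-25). The higher genes included 1 member of those lists, Tph1 (odds ratio 1.04, exact p = 1). Among the 33 lower genes on the tissue lists, Tff3, Fabp2, Mucl2, Npy and Cyp1a2 were also recalled from published work on Aire, which included cells of this kind. Fisher's test takes genes as independent, which genes read on the same 6 arrays are not. On all 3 Aire-deficient arrays, 27 of the 79 lower genes lay under the dim limit of 5.53. Without reference to a variance model, 333 genes were lower and 236 higher by at least 2-fold with no overlap between the groups. The balance of these counts turned round on the values as deposited (278 lower and 328 higher). It also did so without wild-type array 1 (366 and 409) and without wild-type array 3 (341 and 392), where the filter ran anew, but not with the genes of the 6-array filter kept, an alternative added after the data were seen (447 and 422, and 425 and 412). No overlap in either direction was seen for 21.3% of the tested genes, where chance gives 10% for 3 against 3 arrays. These genes were split nearly evenly, with 639 lower and 629 higher.

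The balance of the calls depended on the scaling and on the pairing of the arrays. On the values as deposited 80 genes were lower and 63 higher, a share of 55.9% lower, and after median scaling 84 were lower and 36 higher, a share of 70%. The median change of all genes was 0.18 on the values as deposited and 0.05 after quantile normalization. With the replicate number as a block 220 genes were lower and 154 higher, a share of 58.8% lower, and these included all 79 and all 23 of the genes called without it. With 1 array left out the lower and higher counts were 12 and 3 without wild-type array 1, 6 and 4 without wild-type array 2, 51 and 8 without Aire-deficient array 1, 20 and 1 without Aire-deficient array 2, and 38 and 8 without Aire-deficient array 3. Without wild-type array 3 no gene passed in the limma fit, although 381 genes were lower and 451 higher at an unadjusted p under 0.05. Each call was lost in at least 1 of those fits, while each of the 79 and 23 genes kept its direction in every such fit that tested it. Genes called on the same 6 arrays can hardly turn when 1 array is left out, so the kept direction is no separate evidence. With the genes of the 6-array filter kept, 6 genes were lower and 2 higher without wild-type array 3. With a term for 3' bias, also added after the data were seen, 72 genes were lower and 25 higher, and 27 of the lower and 8 of the higher calls were lost. The lost lower genes had a median change of -2.36 (median SE 0.50) before and -2.05 (0.47) with the term, and the lost higher genes 1.64 (0.35) and 1.51 (0.36). Of these 35 genes, 29 had a change nearer to 0 and 27 a larger SE with the term. The named genes among them, Epyc, Il12a, Cck, Col6a3, Csn1s2a, Nppb, Rsad2 and Tnnt1, all had a larger SE, and 7 of the 8 a change nearer to 0.

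**Figure D1:**
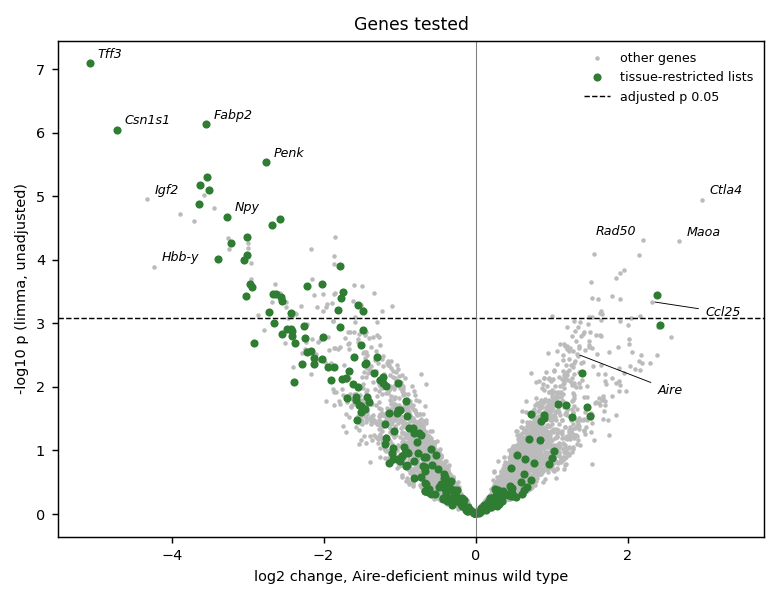
Log2 change of each of the 5950 tested genes (x axis, Aire-deficient minus wild type) against minus log10 of its unadjusted limma p (y axis); green points are members of the tissue-restricted lists and the dashed line marks an adjusted p of 0.05. Of the 79 genes past the line on the left, 33 are green, against 1 of the 23 on the right.

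The largest fall was that of Tff3, a trefoil peptide of intestinal goblet cells, from 75.5 (SD 0.65, n = 3) to 2.24 (SD 0.23, n = 3), at least 13.6-fold. Csn1s1, which encodes a milk casein, fell from 63.5 to 2.42, at least 11.5-fold. Igf2, a fetal growth factor, fell from 138 to 6.89, and Hbb-y, an embryonic globin, fell from 65.1 to 3.47. Ly6g, known as a surface marker of granulocytes, fell from 26.6 to the floor of 1.8 on all 3 Aire-deficient arrays, at least 4.81-fold. Mt4, a metallothionein of stratified epithelium, fell from 48 to 3.69 (at least 8.67-fold). The gut hormone gene Gip fell from 35.1 to 2.8 (at least 6.34-fold), and the enamel gene Amelx fell from 35.9 to 2.9 (at least 6.48-fold). The tachykinin gene Tac2 fell from 47 to 3.95, the intestinal fatty acid binding protein gene Fabp2 from 39.1 to 3.35 (at least 7.06-fold), Mucl2 from 41.3 to 3.56, and the fibrinogen chain gene Fgg from 32.9 to 2.88 (at least 5.95-fold). Adjusted p for these 12 genes, which had the largest falls among the called genes, ranged from 0.000477 for Tff3 to 0.0206 for Hbb-y. The second probe sets of Igf2 and Hbb-y were too dim to be tested. Probe sets whose design allows binding to several family members, as for Hbb-y, Igf2, Amelx and Mucl2, may report on the family and not on 1 gene. A second probe set of Mucl2, of a design without that limit, gave 54.1 and 2 (unadjusted p = 3.46e-06).

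**Figure D2:**
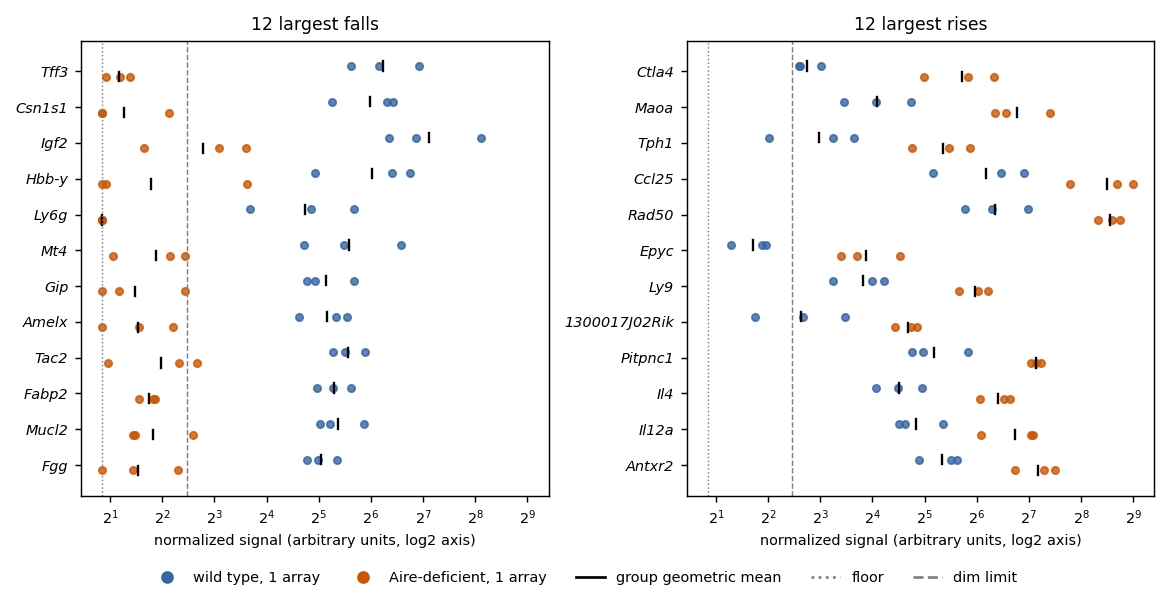
Normalized signal (x axis, arbitrary units, log2 scale) of the 12 genes with the largest falls and the 12 with the largest rises among the called genes; each point is 1 array, black bars are geometric means of 3 arrays, and dotted and dashed lines mark the floor of 1.8 and the dim limit of 5.53. In each of these genes the 3 wild-type and the 3 Aire-deficient arrays do not overlap.

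Taken as 1 set, the tissue-restricted genes were lower in the Aire-deficient cells. The set held 250 tested genes with a median log2 change of -0.62, and 33 fell and 1 rose over all genes tested, or 75 fell and 3 rose when adjusted over the list alone. The set was lower than other genes by camera (p = 4.88e-16, or p = 7.79e-08 and a median of -0.31 without a filter on dim signals), and also with an estimated correlation (p = 0.0145), and its members moved down on balance by fry (p = 0.00222). With signals under the dim limit raised to it, the median was -0.41. Leaving out 1 array at a time gave medians of -0.69 to -0.38, the latter without wild-type array 2, or -0.61 without that array when the genes of the 6-array filter were kept.

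The liver list had the smallest camera p with the preset correlation. Of 37 tested liver genes 10 fell over all genes and 16 when adjusted over the list alone, the median change was -1.11, and the camera adjusted p was 6.2e-11 over 31 lists. Besides Fgg, Apoa1, the main apolipoprotein of high-density lipoprotein, fell from 58 to 9.71, Mup3, a major urinary protein, from 26.5 to 2.85, and Itih3, a plasma protease inhibitor chain, from 14.5 to 1.8 (at least 2.62-fold). Major urinary protein genes are close relatives, so their probe sets may not separate them. Of 16 intestinal genes 5 fell, or 7 when adjusted over the list alone (median -0.77, camera adjusted p = 9.36e-07). Those 5 included Tff3, Fabp2, Gip and the gut hormone gene Cck, which fell from 11.5 to the floor (at least 2.07-fold). With an estimated correlation the adjusted p was 0.181 for both the liver and the intestinal list. No list passed camera after adjustment with an estimated correlation, so the camera calls of lists rest on the preset correlation of 0.01. By fry the liver and intestinal lists passed without the block (adjusted p = 0.00514 for both) but not with it (0.0584 for both).

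Keratinized epithelium, secretory glands, islet and exocrine pancreas were also lower as lists. Of 36 keratinized epithelium genes 4 fell, or 13 fell and 1 rose when adjusted over the list alone (median -0.84, camera adjusted p = 2.19e-07, adjusted p = 0.234 with an estimated correlation). They were Sprr1b, a precursor of the cornified envelope, from 229 to 66.4, Krt4, a keratin of mucosal epithelium, from 40.7 to 14.6, and the calcium-binding proteins S100a8, from 207 to 31.4, and S100a9, from 61.4 to 8. S100a8 and S100a9 are also abundant in neutrophils, and they fell along with Ly6g. A second probe set of Sprr1b gave 101 and 89.3, and the fall of Krt4 was lost on the values as deposited (adjusted p = 0.0684). With a floor at the 40th percentile the median of the keratinized epithelium list was -0.49 (camera adjusted p = 1.14e-07). The secretory gland list of 14 genes had a median of -1.25 (camera adjusted p = 3.26e-06, adjusted p = 0.292 with an estimated correlation), and Mucl2 fell over all genes, or 7 members when adjusted over the list alone. By fry the secretory gland list did not pass (adjusted p = 0.0935). Scgb1a1, a secretoglobin of airway epithelium, measured 62.3 in wild type and 13.1 in Aire-deficient cells (adjusted p = 0.0554, or 0.00414 with the block).

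The islet list of 7 genes had a median of -1.6 (camera adjusted p = 0.000548, adjusted p = 0.243 with an estimated correlation), and 1 of them fell over all genes, or 4 when adjusted over the list alone. Chgb, a secretory granule protein, fell from 32.7 to 7, and Iapp, the islet amyloid peptide, measured 47.4 and 11.8 (adjusted p = 0.0662, or 0.00543 with the block). Of 13 exocrine pancreas genes 2 fell, or 5 when adjusted over the list alone (median -0.41, camera adjusted p = 0.00105, adjusted p = 0.234 with an estimated correlation). Reg3b, a secreted lectin, fell from 59.3 to 9.21, and Ctrb1, a chymotrypsinogen, from 51.4 to 15.3.

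Neural genes moved both ways. Of 22 tested, 4 fell and 1 rose, or 7 and 3 when adjusted over the list alone (median -0.42, camera adjusted p = 0.0264, adjusted p = 0.321 with an estimated correlation). The neuropeptide genes Penk, from 129 to 19.2, Npy, from 18.3 to 1.89 (at least 3.3-fold), and Tac1, from 20.4 to 5, fell, while Tph1, the first enzyme of serotonin synthesis, rose from 7.85 to 41.1. A second probe set of Penk gave 28.6 and 31.2. The neural call was lost without a filter on dim signals, where the median of 43 genes was -0.09 (adjusted p = 0.289). It was also lost without wild-type array 2 (median -0.43, adjusted p = 0.112) and without wild-type array 3 (median -0.46, adjusted p = 0.0611). In the cartilage, bone and tooth list of 6 genes Amelx was the member that fell (median -0.8, camera adjusted p = 0.0264, adjusted p = 0.243 with an estimated correlation), and the call was lost without Aire-deficient array 3 (adjusted p = 0.0831) and with a floor at the 40th percentile (median -0.38, adjusted p = 0.0728). Without a filter on dim signals the median of 17 such genes was 0.02 (adjusted p = 0.667).

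Other tissue lists did not pass as sets by camera in this fit, although some held genes that fell. By fry the mammary (adjusted p = 0.0251), kidney (0.0354) and pituitary (0.038) lists passed without the block, but not with it (0.107, 0.0651 and 0.152). The list medians were -0.37 for 7 pituitary genes (camera adjusted p = 0.121), -0.35 for 10 heart genes (0.148), -0.35 for 13 testis genes (0.177), -0.35 for 10 eye genes (0.28), -0.39 for 5 kidney genes (0.352), -0.26 for 7 adipose genes (0.352) and -0.09 for 22 skeletal muscle genes (0.352). The skeletal muscle median turned to 0.06 on the values as deposited, and the pituitary list passed there with an adjusted p of 0.0299. Without a filter on dim signals the heart list of 16 genes passed (median -0.35, adjusted p = 0.0397). Pomc, the precursor of several pituitary hormones, fell from 35.4 to 4.38, Nppb, a cardiac natriuretic peptide, from 12.6 to 2.15 (at least 2.28-fold), and Tnnt1, a troponin of slow muscle, from 23.1 to 6.59. For the 5 mammary genes the median was 0.29 and the mean was -1.16, which differ in sign (camera adjusted p = 0.352, direction down). Csn1s1 and Csn1s2a fell, the latter from 21.8 to 2.69, whereas the caseins Csn2, 391 and 647, and Csn3, 11.3 and 21, were higher without passing over all genes (adjusted p = 0.254 and 0.257). Lists with fewer than 5 tested genes were not tested as sets, and their median changes were -1.03 for 4 stomach genes, -0.76 for 4 lung genes, -0.79 for 4 ovary genes, -0.63 for 3 genes of male accessory glands, -0.42 for 3 placental genes and 0.41 for 4 genes of thyroid, parathyroid and adrenal. Of the ovary genes 2 lay below 0 and 2 above. Among the latter, Zp2 measured 34.1 and 90.3 (adjusted p = 0.128), or 46.5 and 56.5 on another probe set.

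**Figure D3:**
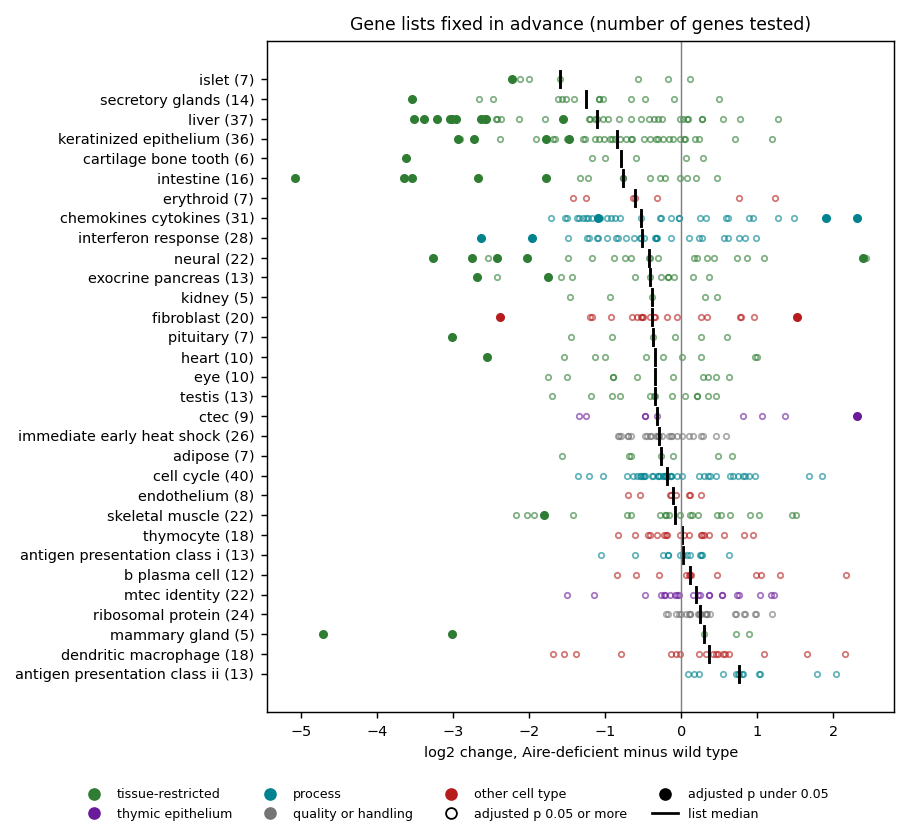
Log2 change (x axis, Aire-deficient minus wild type) of each tested member of the gene lists with at least 5 tested genes, coloured by kind of list; filled points passed an adjusted p of 0.05 over all genes and black bars are list medians. Medians run from -1.6 for islet to 0.76 for class II antigen presentation, and the members of the class II list all lie above 0.

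A list of 10 genes recalled from published work on Aire-dependent transcripts had 8 tested members, of which 5 fell, or 7 when adjusted over the list alone (median -3.33). That work included cells of this kind, so the list is not independent evidence of its direction. Its genes also stand on the tissue lists, which to that extent are not independent either. Besides Tff3, Fabp2, Mucl2 and Npy, Cyp1a2, a hepatic cytochrome, fell from 19.8 to 1.89 (at least 3.57-fold). Oxt, the oxytocin precursor, measured 22.6 and 3.86 (adjusted p = 0.0651, or 0.0246 with the block), and Zp3, an egg coat protein, 11.3 and 2.38 (adjusted p = 0.0662, or 0.035 with the block). The probe sets of insulin Ins2 disagreed: the one with the higher mean over the 6 arrays, used for the gene, gave 10.9 and 11.7, while the other gave 31.3 and 1.85 (unadjusted p = 0.00165). Crp, Gad1 and Mbp, recalled as transcripts that did not need Aire, had a median change of -0.02, and their values were 10.8 and 10.6, 21 and 13.4, and 34.9 and 63.2. A second probe set of Mbp gave 13.1 and 9.28.

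The genes that rose included a receptor of T cells, cytokines and a chemokine. Ctla4, an inhibitory receptor of activated T cells, rose from 6.69 (SD 0.24, n = 3) to 52.7 (SD 0.68, n = 3), or 7.88-fold. Maoa, a mitochondrial monoamine oxidase, rose from 17 to 109, and Tph1 by 5.23-fold. Ccl25, a chemokine that attracts thymocyte precursors, rose from 72.4 to 360, and Rad50, a component of a DNA break repair complex, from 81.4 to 374. Epyc, a small proteoglycan of cartilage, rose from 3.28 to 14.7 (at least 2.65-fold), Ly9, a receptor of lymphocytes, from 14.1 to 62.5, and 1300017J02Rik from 6.2 to 25.5. Pitpnc1 rose from 36.5 to 141, Il4 from 22.6 to 84.7, Il12a from 28.4 to 106 and Antxr2 from 40.3 to 145. Adjusted p for these 12 genes, the largest rises among the called genes, ranged from 0.00669 for Ctla4 to 0.0482 for 1300017J02Rik. A second probe set of Il4 gave 5.23 and 24.7 (unadjusted p = 0.000296). The call of Epyc was lost after median scaling (adjusted p = 0.0519).

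Genes of class II antigen presentation lay higher together in the Aire-deficient cells. All 13 tested members had a change above 0, with a median of 0.76 (camera adjusted p = 6.8e-06, adjusted p = 0.265 with an estimated correlation), and 8 were higher when adjusted over the list alone. None passed over all genes in the limma fit, while 8 had an unadjusted p under 0.05. H2-Ab1, a chain of the presenting molecule itself, measured 653 and 1131 (adjusted p = 0.149, or 0.0485 with the block), and H2-Eb1, another such chain, 978 and 1618 (adjusted p = 0.128). H2-DMb1, part of the peptide exchange factor, measured 86.3 and 176 (adjusted p = 0.125, or 0.0453 with the block), and H2-Ob, part of its inhibitor, 8.21 and 33.6 (adjusted p = 0.111, or 0.0168 with the block). The list median was 1.09 on the values as deposited. The 18 tested marker genes of dendritic cells and macrophages had a median change of 0.37 (camera adjusted p = 0.409) and moved both ways. Among them Cd68 measured 6.85 and 21.5 (adjusted p = 0.0661, or 0.0234 with the block) and Fcer1g 2.53 and 11.2 (adjusted p = 0.103, or 0.0364 with the block), whereas Cd14 measured 148 and 45.9 (adjusted p = 0.0626, or 0.00595 with the block) and Csf1r 30.8 and 10.6 (adjusted p = 0.327). Cd83, a maturation marker of dendritic cells that stands here on the list of cortical epithelium, measured 27.7 and 57.9 (adjusted p = 0.195, or 0.0381 with the block). In the list of B and plasma cells Pax5 measured 2.95 and 13.3 (adjusted p = 0.121, or 0.0306 with the block) and Blk 26.3 and 64.6 (adjusted p = 0.226, or 0.0238 with the block).

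Interferon response genes were lower as a list, with 2 of 28 members falling by either adjustment (median -0.51, camera adjusted p = 0.00528, adjusted p = 0.233 with an estimated correlation). The median of the interferon response list was -0.23 on the values as deposited (camera adjusted p = 0.015). Ifit3 fell from 21.2 to 3.39 (at least 3.82-fold) and Rsad2, an antiviral enzyme, from 27.9 to 7.13. Chemokine and cytokine genes moved both ways: Il12a and Ccl25 rose and the neutrophil chemokine Cxcl1 fell from 614 to 288, or 4 rose and 2 fell when adjusted over the list alone. The fall of Cxcl1 was lost on the values as deposited (adjusted p = 0.236) and after median scaling (adjusted p = 0.138). The median of the 31 chemokine and cytokine genes was -0.54 (camera adjusted p = 0.122, or 0.0421 with the block). By fry this list passed without the block (adjusted p = 0.0354) but not with it (0.0705). Class I presentation genes had a median of 0.03 (13 genes, camera adjusted p = 0.921) and cell cycle genes one of -0.19 (40 genes, 0.679).

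Genes that mark medullary epithelium did not shift as a list (22 genes, median 0.19, camera adjusted p = 0.352). Epcam, which encodes the epithelial adhesion molecule, measured 197 and 89.2 (adjusted p = 0.11, or 0.0295 with the block), and Krt18, a simple epithelial keratin, 85.2 and 175 (adjusted p = 0.209, or 0.0499 with the block). Cd80, which encodes the B7.1 molecule of the sort and was chosen after its values were seen, measured 8.74 and 14.5 (adjusted p = 0.459). The list of cortical epithelium (9 genes, median -0.31, mean 0.19, camera adjusted p = 0.352) included Ccl25, which rose. Of its 9 genes 4 lay above 0 and 5 below, and 4 rose and 1 fell when adjusted over the list alone. Kitl measured 16.1 and 41.2 (adjusted p = 0.0771) and Ly75 37.9 and 66.8 (adjusted p = 0.245). At the 60th percentile filter 5 members were tested and the list was higher (median 1.06, camera adjusted p = 0.00382).

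Lists of other cell types that the sort could carry did not pass in the main fit. Median changes were 0.01 for 18 thymocyte genes (camera adjusted p = 0.921), 0.12 for 12 genes of B and plasma cells (0.273), -0.38 for 20 fibroblast genes (0.267), -0.11 for 8 endothelial genes (0.62) and -0.62 for 7 erythroid genes (0.42). The thymocyte median turned to -0.04 on the values as deposited and -0.16 after median scaling, and the endothelial median turned to 0.01 with a floor at the 40th percentile. Of the fibroblast list S100a4 rose from 35.5 to 102 and the collagen gene Col6a3 fell from 20.3 to 3.89. Ribosomal protein genes were slightly higher as a list (24 genes, median 0.25, camera adjusted p = 0.0187, adjusted p = 0.321 with an estimated correlation), a call lost without wild-type array 1 (adjusted p = 0.133), with a floor at the 40th percentile (0.0504) and without a filter on dim signals (0.0524). The ribosomal median was 0.57 on the values as deposited and 0.45 after median scaling. By fry the ribosomal list did not pass (adjusted p = 0.0817). Immediate early and heat shock genes, which respond to cell handling, had a median of -0.3 (26 genes, camera adjusted p = 0.0819, or 0.0214 with the block), which turned to 0.03 on the values as deposited. The labels put both sexes in each pool. The Y-linked Eif2s3y measured 22.8 and 43.9 (adjusted p = 0.297) on a probe set that may bind family members, while the Y-linked Kdm5d and Uty, chosen after their values were seen, lay under the dim limit on all 6 arrays. Xist, transcribed from the inactive X chromosome, measured 140 and 91.9 (adjusted p = 0.72). It varied widely within the groups, with 139, 380 and 51.5 on wild-type arrays 1 to 3. On Aire-deficient arrays 1 to 3 it measured 65.7, 180 and 65.7, so array 2 was the highest in each group.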

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

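The tests with a 3' bias term, with the block but without both arrays numbered 2, and with arrays left out while the 6-array gene set was kept were chosen only after the results were seen. The tissue-restricted genes as a set stayed lower in each of the 25 alternatives that tested it, with medians of -0.69 to -0.31. The fits with the 3' bias term tested neither this set nor any gene list. Every tested member of the 79 lower and 23 higher genes kept its direction in every alternative, which genes called on these same arrays could hardly fail to do. The counts differed with the scaling, the floor, the filter and the fit.

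On values as deposited 63 genes were higher and the Aire probe set passed (1.64), and after median scaling 36 were higher. With a floor at the 5th percentile 2 lower and 0 higher neighbouring pairs were called, and with one at the 40th percentile 46 genes were higher with 8 lower pairs. Without a filter 8251 genes were tested, 12 were lower and 4 higher, and 0 neighbouring pairs were called in either direction. At the 60th percentile filter 213 genes were lower by 2-fold and separated. Without a variance trend 11 genes were higher with 0 higher pairs. Array weights gave 139 lower and 67 higher genes, with 15 and 4 pairs.

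The replicate block gave 220 lower and 154 higher genes, an Aire change of 1.33 past the threshold, and 25 lower and 9 higher pairs. With the 3' bias term in addition these were 297, 202, 1.14, 36 and 15, and with both arrays numbered 2 left out they were 207, 146, 1.19, 21 and 11. The 3' bias term alone gave 72 lower and 25 higher genes and 2 higher pairs. Beyond those named in the report, the block changed the camera call of no gene list. With the block no tissue list passed by fry, where the smallest adjusted p was 0.0584, for liver and intestine. The fry adjusted p of class II presentation went from 0.038 to 0.134 with the block, and that of interferon response from 0.0103 to 0.0584. Of the 166 named genes the block moved 33 past the threshold and lost none. Among those named genes the calls lost numbered 41 without a filter, 12 without a variance trend, 8 with the 3' bias term, and 2 to 6 in each of the other scaling, floor, filter, robust and probe set alternatives, with array weights losing none.

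Leaving out 1 array gave 0 to 51 lower genes, 0 to 11 higher genes, 270 to 447 genes lower and 231 to 422 higher by 2-fold and separated, 0 to 4 lower and 0 to 1 higher pairs, and Aire changes of 1.02 to 1.62. With 2 wild-type arrays left, a gene absent from the mutant cannot lie above the limit on 3 arrays, so that 51 or 52 of the 79 genes were tested. With the 6-array genes kept, 38 were lower without wild-type array 1, 23 without array 2 and 6 without array 3. Fewer samples lower the power. Settings that alter the variance model or the block do not enter the 2-fold counts.

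Ins2 reversed to -2.5 with a floor at the 40th percentile and to -1.99 with the mean of its probe sets, since its 2 probe sets disagree. The cartilage, bone and tooth list reversed to 0.0205 without a filter, with more members tested, and the cortical epithelium list to 1.06, past the threshold, at the 60th percentile filter, with 5 of 9 members tested. Except where a construction is named, the cause was not tested. Dim signals limit the folds: below the floor of 1.8 no order is read.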

Other observations

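The tests of T-lineage, dendritic cell, B cell and granulocyte carry-over and of neighbours among the genes called with the block were chosen only after the results they bear on were seen. The genes named in the next paragraph were chosen after their values were seen, except S100a4, S100a8, S100a9, Ly6g, Il4 and Rad50, and so were Hp, Mpo, Mmp9, Csf3r, Chil3, Lcn2, Lyz2, Tyrobp, Cybb and Fcgr3.

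Granule proteins of neutrophils were among the transcripts that fell in Aire-deficient cells. Ltf, which encodes lactoferrin, fell from 24.9 to 2.29 (at least 4.49-fold), Ngp from 25.4 to 2.65 (at least 4.59-fold), the cathelicidin gene Camp from 95.5 to 21.4 and Pglyrp1 from 34.4 to 9.48, beside Ly6g, S100a8 and S100a9. In the S100 gene family S100a4 and S100a6 rose, the latter from 186 to 548, whereas S100a8, S100a9 and S100a10 fell, the last from 116 to 41.8. Around Il4, which rose as the nearby Rad50 did, Il13 measured 38.7 and 55.7 (adjusted p = 0.451), Kif3a 2.56 and 8.07 (adjusted p = 0.208) and Il5 10.8 and 4 (adjusted p = 0.169). Il9 fell from 29.2 to 4.

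For the lower genes, the first pattern weighed, the 10 splits of the 6 arrays are too few for a share under 0.05, and 1 split, the real one, gave as many genes in each count: 79 lower genes against at most 0 in another split, 23 higher against 0, 333 lower and 236 higher by 2-fold and separated against 123, and a tissue-set median of -0.62 against a highest size of 0.464. Among the 4 splits that part all pairs, the highest of the others were 0, 0, 37, 37 and 0.383, and with the block the other 3 called 0 genes against 374. To weigh the 3' bias of wild-type array 2 as the whole cause, that array was left out. The 79 genes then had a median change of -2.43 (95% interval -2.71 to -2.14, median SE 0.49), against -2.55 (median SE 0.45) with it, or -1.96 over the 51 that passed the filter anew. The intervals of medians here and below come from resampling genes, which are read on the same arrays and are not independent. They leave out the spread between pools and may be too narrow. Of the 79, 22 were still called and 58 had a larger SE. Their fall was thus not seen on that array alone, which met the bound set in advance. Genes chosen on all 6 arrays could hardly lose their fall without 1 of them, so the test shows no more than that. A 3' bias shared by the wild-type arrays, whose ratios were higher in each same-number pair, is not separated from genotype by leaving out 1 array. Carry-over of granulocytes in the wild-type pools may account for the granule genes: the 19 tested granulocyte markers had a median of -1.1 with an interval of -2.16 to 0.47, so it stays open, and the sort excluded CD45-positive cells. Of these markers 7 fell, and the other 12 went both ways: Hp measured 43.7 and 12.7 (adjusted p = 0.0569), Mpo 11.4 and 3.27, and Mmp9 27.7 and 12.9, whereas Csf3r measured 15.1 and 24.8, Chil3 32.4 and 44.9, Lcn2 21.8 and 18.5, Lyz2 122 and 120, Tyrobp 8.35 and 7.98, and Fcer1g 2.53 and 11.2. Cybb measured 3.67 and 7.81, Fcgr3 5.3 and 7.88, and Ptprc 5.83 and 8.62. The 7 prompted the test, so the median of all 19 partly restates their fall. The other 12 had a median of 0.22, but as they were set apart for not being called, that median excludes nothing.

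The higher genes are the second pattern. Without wild-type array 2 their median was 1.63 (95% interval 1.54 to 1.95, median SE 0.33) against 1.84 (median SE 0.35), and 6 of the 23 were still called with fewer arrays. Their rise was thus not seen against that array alone. As these genes were chosen on all 6 arrays too, the test shows no more than that, and a 3' bias shared by the wild-type arrays stays open. Alleles of the 129 strain carried along with the disrupted gene could raise genes near Aire, but 0% of the 23 lay among the 100 tested genes nearest to it, with an exact upper limit of 14.8%. Carry-over of T-lineage cells, a possible source of Ctla4, Il4 and Ly9 although the sort excluded CD45-positive cells, would bring their abundant transcripts, and the thymocyte list had a median of 0.012 (interval -0.273 to 0.279). Rare cell types outside these lists and the genotype itself stay open, and the 10 splits are too few to weigh chance.

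Class II presentation genes, with a median of 0.76, are the third pattern. Carry-over of dendritic cells or macrophages stays open: their list had a median of 0.37 (interval -0.1 to 0.55), but its members go both ways, and Cd68 and Fcer1g lay above 0.76 by more than 2 SE. Carry-over of B cells, which like the former carry the CD45 that the sort excluded, stays open too: their list had a median of 0.12 with an interval of -0.11 to 1.01, and Pax5 lay above 0.76 by more than 2 SE. Fcer1g lay at the floor on wild-type arrays 1 and 2 and Pax5 on wild-type arrays 2 and 3, so these folds are uncertain. Other probe sets of Cd68, Fcer1g and Pax5 were too dim to be tested. Without wild-type array 2 the class II median was 0.58 (interval 0.36 to 0.88), an interval too wide to tell how much of it was kept, so a part played by that array's 3' bias cannot be told apart from a difference between genotypes. More mature or more activated epithelial cells in the Aire-deficient sort also stay open, untested.

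A hypothesis written before its test was that neighbouring genes change together. Among the lower genes 4 neighbouring pairs were found, against a mean of 1.04 in 10000 random draws (1-sided permutation p = 0.0198). They were Mcpt2 and Gzmb, S100a8 and S100a9, Mup5 and Mup3, and Saa3 and Saa2, so that 1 pair had different name stems (permutation p = 0.636), and cross-hybridisation between relatives may account for part of this. Different name stems, as of Mcpt2 and Gzmb, do not exclude that genes are relatives. Among the higher genes 1 pair was found, Col14a1 and Mrpl13 (permutation p = 0.0784), no more than the upper limit of 1 in the draws, a bound that 0 or 1 pair always meets with so few genes, so it decides nothing. With the block 25 lower pairs were found against a random mean of 8.07 (permutation p = 1e-04, the smallest the draws can give), and 9 higher pairs against 3.94 (permutation p = 0.0154). Of these, the pairs with different name stems numbered 11 among the lower genes (permutation p = 0.15) and 6 among the higher (permutation p = 0.172). Over all 5656 neighbouring pairs with different stems the log2 changes correlated at 0.0678 across genes, which are not independent replicates (permutation p = 1e-04), and 3 other splits gave as much, with a highest of 0.08. None of those 3 parts all pairs, and the 3 others that do gave 0.0302 to 0.0387. The test written in advance had asked for a value above all other splits, and 1 other split as high was to count against the hypothesis. By that rule the prediction failed. The splits that gave as much mix the pairing with the groups, but the 3 that part all pairs are too few to replace the rule. Of the genes in these pairs, those other than S100a8, S100a9 and Mup3 were chosen after their values were seen.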
